A study of Caenorhabditis elegans with 9 samples.

How the data were processed

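RNA-seq was done on whole wild-type (N2) Caenorhabditis elegans, with 500 animals per sample kept for 12 h in liquid culture. The 9 libraries fall into 3 groups of 3: animals without a nanomaterial (control), animals with graphene oxide (GO, a sheet of carbon carrying oxygen groups) and animals with amino-functionalised GO (GONH2). Per the labels, animals were homogenised with beads in TRIzol, RNA was purified on RNeasy columns, and stranded TruSeq libraries of total RNA were sequenced paired-end on an Illumina HiSeq. The dose and the separate growth of the replicates are not stated in the sources used here, so p values measure the spread between these samples and nothing wider.

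The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 46284 WormBase gene IDs. The aligner, the counting program, the genome build and the version of the annotation are not given in the sources used here. DESeq2 is named per the submitters' processing notes. Its part in the deposited values is not known here, and it was not run again. Gene IDs were matched to symbols, biotypes and positions in the Ensembl release 115 annotation of WBcel235, which named 43325 of them. In 157 genes 1 to 8 libraries were listed at 0 although the median of the libraries above 0 was 10 FPKM or more. The gene cel-mir-8199, described below, was among them. Such zeros were kept as listed in the comparisons, and 74 of the 157 genes were among those tested.

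Values were converted to log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 of the 9 libraries were kept, which left 12849 genes, 12242 of them protein-coding. Of the rest, 25596 genes were listed at 0 in every library. A linear model with group as its only term was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend (prior degrees of freedom 2.47, residual degrees of freedom 6). The moderated test was run for GO minus control, GONH2 minus control and GONH2 minus GO, and the moderated F test for any difference among the groups. P values were adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05. Because the values are FPKM, no method for read counts was used.

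Lists of genes, 37 in number, were tested with camera at its preset correlation of 0.01, with p values adjusted over the 37 lists. Camera compares a list with the other genes tested, so a list is called higher or lower relative to them. The median log2 difference over all genes tested was 0.024 for GO minus control, 0.0031 for GONH2 minus control and −0.024 for GONH2 minus GO. Each list was also tested with camera at an estimated correlation and with fry, which asks whether the genes of a list move on balance in a direction. The adjustment was also repeated over the members of each list alone. The comparisons, the lists, the filter, the thresholds and the rule for naming genes were set before the data were examined. By that rule the genes named in each comparison are the 10 largest rises and the 10 largest falls among called genes that have a symbol and whose groups do not overlap. The rule adds up to 4 members with the smallest p of each list that was called or had at least 3 members past the threshold, and up to 3 abundant members that did not pass. Genes named outside the rule are marked as chosen after their values were seen.

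FPKM carry no read totals, so the depth of each library is unknown. The spacing of the lowest values gave a rough relative depth of 1.15 to 1.243 times that of control replicate 1, but with only 2 to 12.06% of low genes at the modal spacing. No counting interval or floor is therefore given for a value of 0. The median 95% confidence interval of a log2 difference extended 0.217 to each side. On data simulated from these libraries, changes of 1.5-fold were called in 60.4% of planted genes for GO versus control, 61.6% for GONH2 versus control and 57.6% for GONH2 versus GO. At 1.25-fold the shares were 38.8%, 35.2% and 36.4%. These shares rest on 5 simulated data sets per comparison with 50 changed genes at each of 1.25-, 1.5-, 2- and 4-fold, planted on the log2(FPKM + 1) scale. In the real data GONH2 versus control and GONH2 versus GO called only 56 and 17 genes. The adjusted threshold is stricter with fewer calls, so for both GONH2 comparisons the shares are likely too high. Among the calls 3.96%, 6.79% and 4.62% were false.

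Alternatives covered the value added before the logarithm, the filter, 2 other scalings between libraries, the mean-variance trend, array weights, stricter thresholds, fits to 6 libraries, the replicate number as a block, and leaving out each library in turn. After the data had been seen, 4 more were added: zeros set to missing, genes with such zeros left out, a robust prior variance, and protein-coding genes only. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.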

Results

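Gene expression was measured as FPKM in 9 samples of whole wild-type animals, 3 without a nanomaterial (control), 3 with GO and 3 with GONH2, all after 12 h. The FPKM of a library summed to between 955606 and 1010900, and between 12299 and 12676 genes had at least 1 FPKM. Over the 12775 tested genes without the zeros described above, libraries of the same group correlated at 0.986 or more (Pearson's r of log2 values). Libraries of different groups correlated at 0.983 to 0.992. Read totals are unknown, so the depth behind each value cannot be given. FPKM are given as means ± SD over 3 libraries, and changes are differences of log2(FPKM + 1) ± SE. Positions are those of the WBcel235 annotation.

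The comparison of GO with control asks which genes respond to unmodified graphene oxide. Of 12849 genes, 139 were higher and 23 lower in GO, and 28 and 6 of these changed at least 2-fold. At an unadjusted p under 0.05 there were 994 genes. In 1558 of the 12849 genes the GO and control libraries did not overlap, where chance gives 10% of genes. All 162 called genes were among the 1558.

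The largest rises among called genes with a symbol were those of srlf-3, from 5.42 ± 0.947 to 30.9 ± 3.15 FPKM (2.32 ± 0.13, adjusted p = 6.61e-05), and srlf-35 (1.57, adjusted p = 0.00662). dod-19, a gene downstream of the insulin-pathway factor DAF-16, rose from 78.7 ± 14.9 to 206 ± 14.9 FPKM (1.39 ± 0.12, adjusted p = 8.09e-04), and dod-23 from 152 ± 10.1 to 345 ± 26.1 (1.17 ± 0.072, adjusted p = 9.56e-05). dct-17, another gene under DAF-16, rose by 1.21, cdr-2 of the cadmium-responsive family by 1.18, ifas-2 by 1.13, pqn-31 (a glutamine- and asparagine-rich protein) by 1.10, and abf-5, related to antibacterial factors, by 1.09. The adjusted p values of these 5 genes were 0.00393, 0.00569, 0.0132, 4.60e-04 and 0.00424. The C-type lectin gene clec-85 completed the 10 largest rises.

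The acid sphingomyelinase gene asm-3 fell from 3.21 ± 0.403 to 0.283 ± 0.147 FPKM (−1.72 ± 0.13, adjusted p = 4.60e-04). fipr-3, related to fungus-induced proteins, changed by −1.36 (adjusted p = 0.00899), and the C-type lectin genes clec-70, clec-218 and clec-5 by −1.18, −0.94 and −0.86 (adjusted p = 0.0113, 0.00177 and 4.80e-04). pudl-2 and pud-4, of a family named after a rise in daf-2 mutants, changed by −1.01 and −0.72 (adjusted p = 0.0229 and 0.00454). The lipase gene lipl-3 changed by −0.63 and txt-4 by −0.57 (adjusted p = 0.0216 and 0.00924). The microRNA gene cel-mir-8199 was listed at 728, 731 and 242 FPKM in the control libraries and at 0 in all 6 libraries with GO or GONH2, so no fold is given for it. Its annotation (chromosome II, 2136552 to 2137329, 413 bases of exon) includes a primary transcript, and the libraries were of total RNA, so the values are not shown to measure the mature microRNA, and whether the zeros reflect expression was not tested.

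C-type lectins, proteins with a carbohydrate-binding fold of which many are induced by infection, lay higher with GO as a list of 77 genes (camera adjusted p = 1.99e-05; adjusted p = 0.143 with an estimated correlation). Of these, 13 rose and 3 fell over all genes tested, and 21 and 6 when adjusted over the list alone. clec-63 (WBGene00009394) rose from 613 ± 43.4 to 1069 ± 24.4 FPKM (0.80 ± 0.049, adjusted p = 9.44e-05), clec-62 rose by 0.95 ± 0.042 (adjusted p = 2.08e-05) and clec-65 from 94.8 ± 4.70 to 156 ± 2.85 (0.71 ± 0.040, adjusted p = 6.89e-05). These 3 genes lie on chromosome II between 12893062 and 12903336, and clec-64, which lies between clec-63 and clec-65, did not pass the filter. clec-85 (WBGene00021872, chromosome IV, 2850886 to 2855456) rose from 58.6 ± 3.41 to 124 ± 3.76 FPKM (1.07 ± 0.048, adjusted p = 2.08e-05). The abundant members clec-87, clec-88 and clec-91 did not pass (log2 −0.025, 0.044 and −0.030; adjusted p = 0.949, 0.925 and 0.931).

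Lysozymes also lay higher as a list of 10 (camera adjusted p = 2.26e-06; adjusted p = 0.143 with an estimated correlation). lys-7 (WBGene00003096, chromosome V, 3481432 to 3482600) rose from 400.2 ± 6.17 to 688 ± 11.9 FPKM (0.78 ± 0.025, adjusted p = 5.33e-06), the smallest adjusted p among the genes named. lys-4 rose by 0.25 and lys-8 by 0.31 (adjusted p = 0.00418 and 0.0106), while lys-1 did not pass (0.35, adjusted p = 0.182). Adjusted over the list alone, 4 lysozyme genes rose. In the list of 11 infection response genes that depend on the p38 kinase PMK-1 (camera adjusted p = 5.54e-07; adjusted p = 0.143 with an estimated correlation), clec-85, C17H12.8 and dod-24 rose, and 5 genes rose and 1 fell when adjusted over the list alone. C17H12.8, which encodes a CUB-like domain, rose by 1.33 ± 0.12 (adjusted p = 9.90e-04). dod-24 rose by 0.45 (adjusted p = 0.0346), and clec-67 did not pass (0.70, adjusted p = 0.0609). The list shares clec-85 and clec-67 with the C-type lectins, lys-2 with the lysozymes, and dod-24 and dod-22 with the genes lowered by DAF-16.

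**Figure D1:**
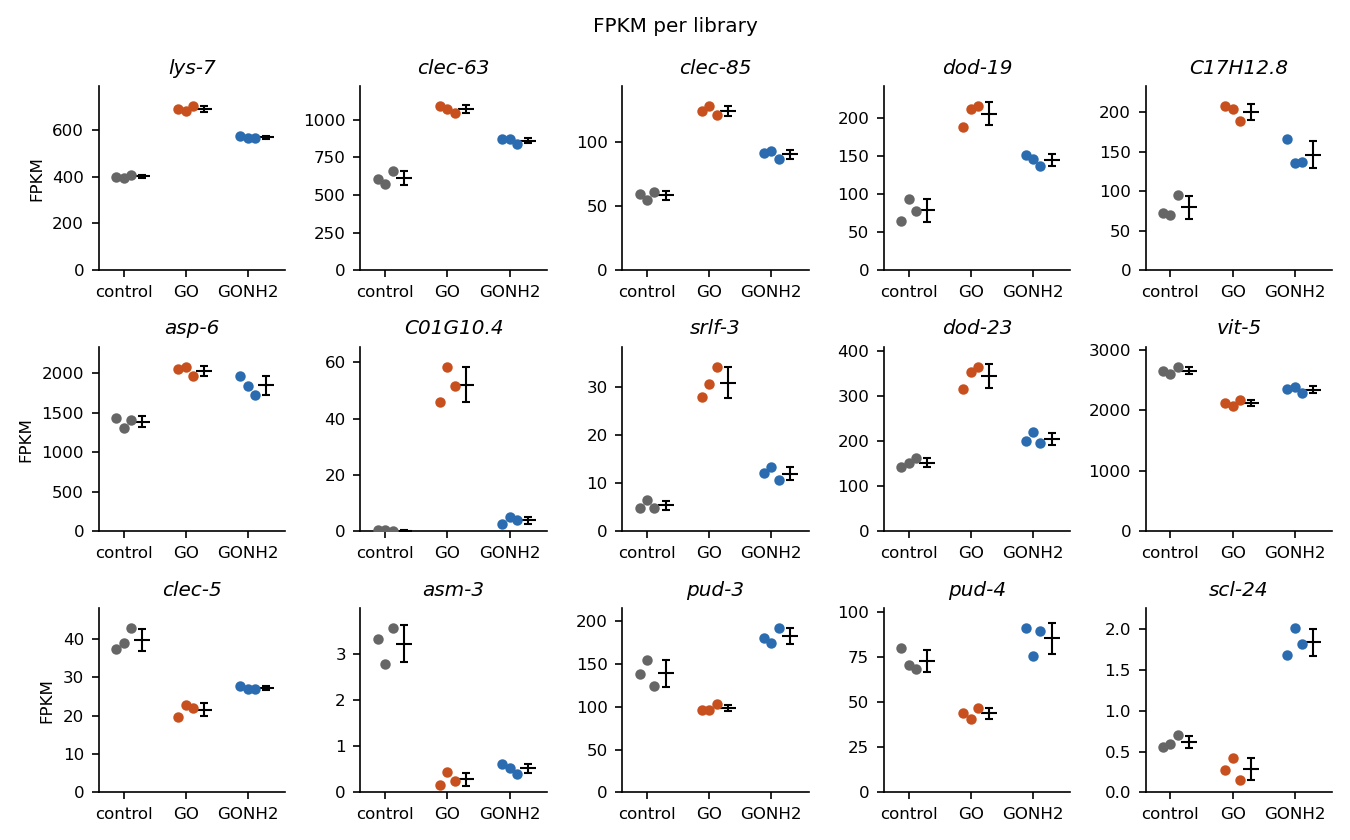
FPKM of 15 named genes in each library (dots), with the mean and SD of each group of 3, for control, GO and GONH2; each panel has its own axis. lys-7 had 400.2 FPKM in control, 688 with GO and 567 with GONH2.

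Of 18 intestinal aspartic and cysteine proteases, 6 rose and 0 fell with GO over all genes, and 9 and 2 when adjusted over the list alone (camera adjusted p = 5.10e-07; adjusted p = 0.157 with an estimated correlation). asp-1 rose from 1234 ± 36.9 to 1704 ± 6.16 FPKM (0.47 ± 0.033, adjusted p = 2.50e-04) and asp-6 from 1388 ± 67.2 to 2031 ± 63.3 (0.55 ± 0.055, adjusted p = 0.00177). asp-3 and cpr-9 rose by 0.35 and 0.42 (adjusted p = 9.27e-04 and 0.00424). The abundant proteases cpr-6, asp-5 and cpr-1 did not pass (log2 0.0068, −2.79 and −0.036); asp-5 was listed at 0 in 1 library of the GO group. The 16 intestine markers, which share asp-1 and cpr-6 with the proteases, were not called as a list (camera adjusted p = 0.179; adjusted p = 0.611 with an estimated correlation; median 0.069). Of these, asp-1 and ges-1 rose (0.40 for the latter, adjusted p = 0.0177) and 0 fell over all genes, or 2 and 1 when adjusted over the list alone.

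Among 7 genes lowered by DAF-16 (camera adjusted p = 9.29e-05; adjusted p = 0.143 with an estimated correlation), dod-19, dod-23, dod-24 and the insulin-like peptide gene ins-7 rose, and the yolk protein gene vit-5 fell; adjusted over the list alone, 4 rose and 1 fell. ins-7 rose by 0.88 (adjusted p = 0.0190). dod-22 and dod-17 did not pass (log2 0.32 and 0.054). The 17 genes raised by DAF-16 were not called as a list (camera adjusted p = 0.786; median −0.0092, mean 0.025). The lysozyme gene lys-7, with the smallest adjusted p among the genes named, belongs to this list too. It was the 1 member that rose, over all genes and adjusted over the list alone. Vitellogenins, the yolk proteins, lay lower as a list of 5 (camera adjusted p = 7.17e-06; adjusted p = 0.143 with an estimated correlation), with 2 falling over all genes and 2 when adjusted over the list alone. The groups overlapped in the list's median deviation from the mean over the 9 libraries, which was −0.0032, 0.29 and 0.18 in the control libraries and −0.28, −0.19 and 0.044 in the GO libraries. vit-5 (WBGene00006929, chromosome X, 3403471 to 3408603) fell from 2658 ± 58.9 to 2120.5 ± 48.8 FPKM (−0.33 ± 0.034, adjusted p = 0.00197) and vit-3 from 551 ± 28.6 to 401 ± 13.9 (−0.45 ± 0.073, adjusted p = 0.0207). vit-1, vit-4 and vit-6 did not pass (log2 −0.31, −0.17 and 0.020).

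Among 60 antimicrobial peptides and saposin-like proteins, 4 genes rose and 2 fell (7 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.308). The saposin-like genes spp-2 and spp-3 rose, spp-2 from 162 ± 21.5 to 301 ± 9.65 FPKM (0.90 ± 0.085, adjusted p = 0.00130) and spp-3 by 0.31 (adjusted p = 0.00327). The abundant spp-5, spp-17 and spp-10 did not pass (log2 0.12, 0.13 and 0.077).

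Cuticle collagens lay lower with GO as a list, although 0 of 75 passed over all genes or when adjusted over the list alone (camera adjusted p = 9.40e-13; adjusted p = 0.143 with an estimated correlation; median −0.11). The smallest p values were those of col-181, col-113, col-39 and col-10 (log2 −0.12, −0.74, −0.57 and −1.08; adjusted p = 0.244 to 0.295). Measured against their mean over the 9 libraries, collagens had medians of 0.11 and 0.16 in control replicates 1 and 2 and −0.0096 in control replicate 3, against −0.094, −0.071 and 0.019 in the GO libraries. Also with 0 members past the threshold over all genes, lists of cytosolic ribosomal proteins (adjusted p = 5.10e-07), proteasome subunits (8.29e-04), muscle markers (0.00422), germline genes (0.00653) and molting genes (0.0232) lay lower, and genes of the endoplasmic reticulum unfolded protein response (0.0455) higher. All 6 had an adjusted p = 0.611 with an estimated correlation. The median was −0.018 for proteasome subunits, −0.016 for muscle markers and −0.024 for both germline and molting genes. These falls are no larger than the median over all genes, 0.024, which had the opposite sign. For the unfolded protein response the median was 0.070. Adjusted over the list alone, 1 molting gene rose, 1 fell, and 0 passed in the other lists. The ribosomal list had a median of −0.024 but a mean of 0.023, and its call was lost without GO replicate 1 (adjusted p = 0.430). The proteasome call was lost without control replicate 3 (0.284) and the germline call without control replicate 2 (0.0602). The unfolded protein response call was lost without any of the 3 control libraries or GO replicate 2 or 3, and the molting call without control replicate 1 or 2 or GO replicate 1 (adjusted p up to 0.368 and 0.292). Both were also lost under median-of-ratios scaling.

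**Figure D2:**
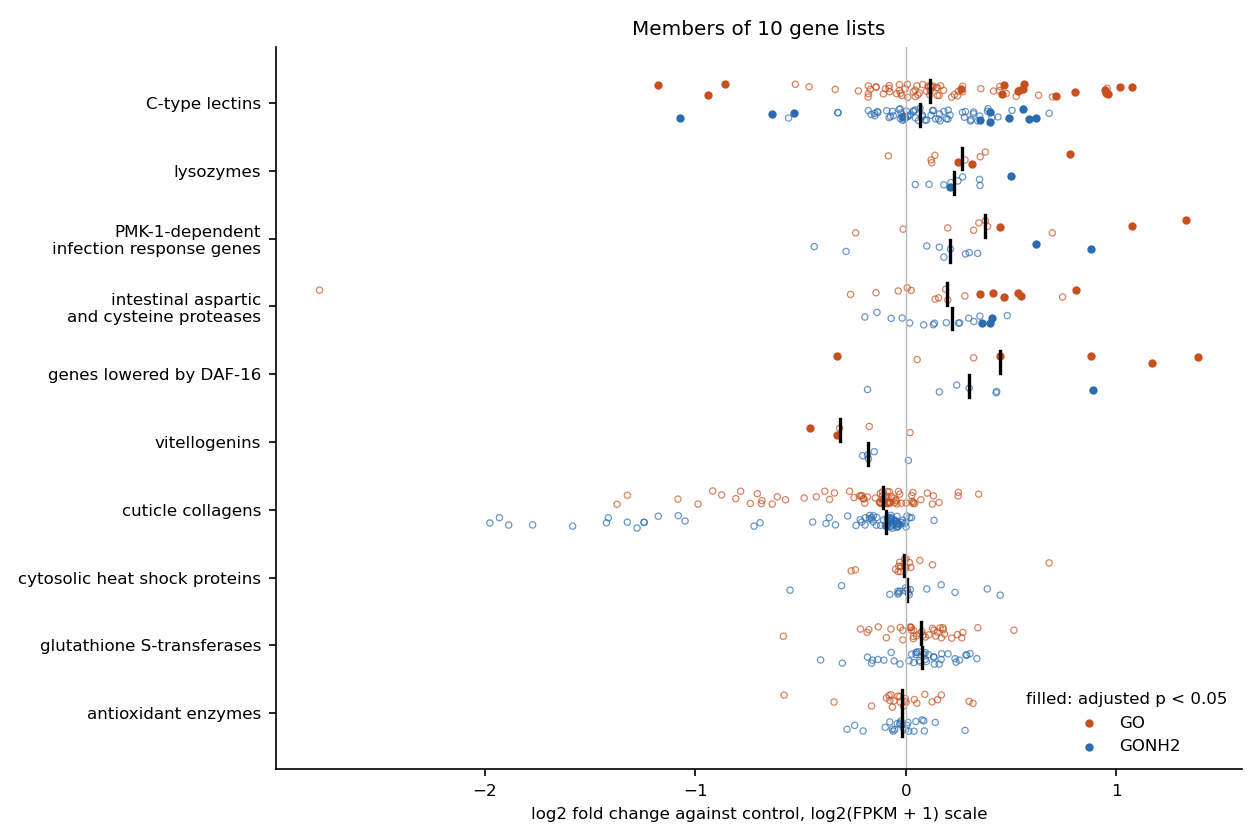
Change against control, as the difference of log2(FPKM + 1), of every tested member of 10 gene lists with GO and with GONH2; filled points have an adjusted p under 0.05 and black bars mark the median. With GO the median was 0.38 for genes that depend on PMK-1 and −0.31 for vitellogenins.

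Apart from the endoplasmic reticulum unfolded protein response, the lists of stress and detoxification genes named next were not called with GO. Camera adjusted p was 0.243 for cytosolic heat shock proteins (median −0.0063, mean 0.011), 0.181 for antioxidant enzymes, 0.489 for glutathione S-transferases, 0.794 for detoxification genes under SKN-1 (median 0.038, tested direction down), 0.481 for cytochrome P450 enzymes (median 0.059, tested direction down), 0.517 for metal and iron response genes (median 0.028, mean −0.076) and 0.328 for the mitochondrial unfolded protein response (median 0.00077, tested direction down). In these 7 lists 0 genes passed over all genes, and 1 SKN-1 gene and 1 metal gene fell when adjusted over the list alone. Among 48 UDP-glucuronosyltransferases 1 gene rose (2 adjusted over the list alone; camera adjusted p = 0.181). The abundant members hsp-1, prdx-2 and gst-1 had log2 changes of −0.0049, −0.038 and 0.027 and did not pass. In all, 13 of 37 lists were called with the preset correlation, 0 with an estimated correlation and 6 by fry, namely C-type lectins, lysozymes, PMK-1-dependent genes, proteases, genes lowered by DAF-16 and vitellogenins; 16 had an unadjusted p under 0.05. In 8 of the 13 the library medians of GO and control overlapped. They did not for C-type lectins, lysozymes, PMK-1-dependent genes, proteases and genes lowered by DAF-16. With the preset correlation, other splits of the same 6 libraries also called 6 to 12 lists.

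Of the 37 calls of named genes in this comparison, 28 stayed at adjusted p under 0.05 in each refit that kept the gene (20 refits for cel-mir-8199, 22 for asm-3 and fipr-3, 23 for the others). All 28 had adjusted p under 0.01 with all libraries, and 13 changed at least 2-fold. cel-mir-8199 is among the 28, but no refit tested its listed zeros. lys-8, dod-24, ins-7, vit-3, ifas-2, clec-70, pudl-2, lipl-3 and txt-4 were lost in at least 1 refit. Without GO replicate 2, 9 named calls were lost and the counts were 92 higher and 15 lower. Without control replicate 1, 2 or 3, 4, 3 and 5 named calls were lost, without GO replicate 1 or 3, 6 and 4, and without GONH2 replicate 2, 1.

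A group of adjacent genes without a symbol on chromosome V, chosen after their values were seen, had the largest rises of all. C01G10.4 (WBGene00007231, 15089740 to 15090059) rose from 0.303 ± 0.263 to 52.0 ± 6.26 FPKM with GO (5.36 ± 0.21, adjusted p = 1.69e-05) and had 3.96 ± 1.19 FPKM with GONH2. C01G10.5 and C01G10.17 rose by 4.17 and 3.34 (adjusted p = 0.00323 and 0.00327). C01G10.5 lies on the opposite strand from the other two. C01G10.7 on one side had between 44.4 and 51.8 FPKM over the 9 libraries, and txt-12 on the other between 0.274 and 1.89.

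**Figure D3:**
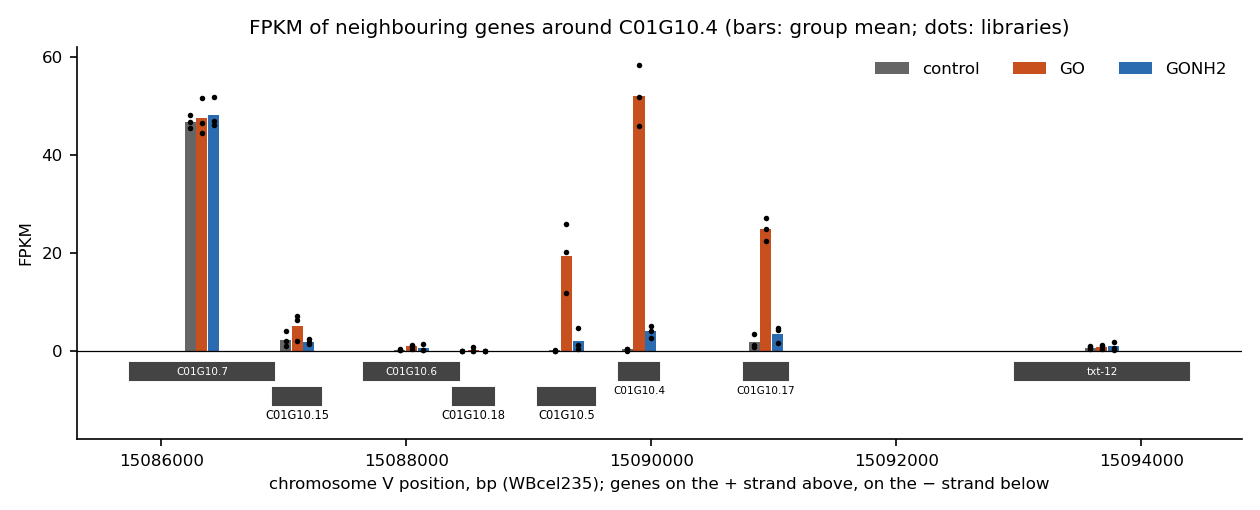
FPKM of 8 adjacent genes on chromosome V, from C01G10.7 to txt-12, in the 3 groups (bars, mean; dots, libraries), above a map of the genes with those on the plus strand above the line and those on the minus strand below. C01G10.4 had 45.9, 58.4 and 51.7 FPKM in the GO libraries.

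The comparison of GONH2 with control asks the same of the amino-functionalised sheets, and 46 genes were higher and 10 lower, of which 3 and 4 changed at least 2-fold. The 46 became 22 and 30 without control replicates 1 and 3, and 20 and 22 without GONH2 replicates 1 and 2. The 10 became 5 without control replicate 1, 6 without GO replicate 2 or 3, and 5, 5 and 4 without GONH2 replicates 1, 2 and 3. At an unadjusted p under 0.05 there were 682 genes, close to the share of 0.05 that chance gives. The groups did not overlap in 1135 of 12849 genes (8.83%), where chance gives 10%. The largest rises with a symbol were srlf-3 (1.02 ± 0.13, adjusted p = 0.0145), dct-17 (0.93, 0.0394), dod-19 (0.89, 0.0227) and scl-24, which encodes an SCP-like extracellular protein (0.81, 0.0387). spp-2, the C-type lectin gene clec-41 and ctsa-4.2, a homologue of cathepsin A, rose by 0.59, 0.56 and 0.55 (adjusted p = 0.0276, 0.0387 and 0.0247). asm-3 fell to 0.517 ± 0.106 FPKM (−1.47 ± 0.13, adjusted p = 0.00343). clec-70, clec-218 and clec-5 changed by −1.07, −0.64 and −0.53 (adjusted p = 0.0438, 0.0345 and 0.0181). pcp-1, which resembles prolyl carboxypeptidases, changed by −0.57, grsp-4, for a glycine-rich secreted protein, by −0.33, and the acid phosphatase gene pho-11 by −0.32 (adjusted p = 0.00459, 0.0465 and 0.0314).

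Lysozymes lay higher with GONH2 (camera adjusted p = 1.95e-09; adjusted p = 0.126 with an estimated correlation). lys-7 rose to 567 ± 5.43 FPKM (0.50 ± 0.025, adjusted p = 1.08e-04) and lys-4 by 0.21 (adjusted p = 0.0264), and 3 lysozyme genes rose when adjusted over the list alone. Of the proteases, asp-1, asp-6 and cpr-9 rose by 0.40, 0.41 and 0.36 (adjusted p = 0.00245, 0.0220 and 0.0227), and asp-3 did not pass (0.19, 0.0509). As a list the proteases lay higher (camera adjusted p = 4.55e-08; adjusted p = 0.170 with an estimated correlation), with 8 rising and 1 falling when adjusted over the list alone. Of the C-type lectins 7 rose and 3 fell, or 13 and 4 adjusted over the list alone (camera adjusted p = 1.16e-04; adjusted p = 0.170 with an estimated correlation). clec-62 rose to 54.2 ± 1.53 FPKM (0.59 ± 0.042, adjusted p = 0.00169) and clec-85 to 90.5 ± 3.25 (0.62 ± 0.048, adjusted p = 0.00245), and clec-150 and clec-50 rose by 0.40 and 0.35 (adjusted p = 0.00245 and 0.00343).

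The genes lowered by DAF-16 lay higher with GONH2 (camera adjusted p = 1.16e-04; adjusted p = 0.170 with an estimated correlation). Only dod-19 passed among them, and dod-23 (0.43, adjusted p = 0.0555) and dod-24 (0.30, 0.348) did not; adjusted over the list alone, 4 rose and 1 fell. In the PMK-1 list (camera adjusted p = 0.00107; adjusted p = 0.418 with an estimated correlation), clec-85 and C17H12.8 rose (0.88 for the latter, adjusted p = 0.0234), irg-4 did not pass (−0.44, 0.236), and 3 rose and 2 fell when adjusted over the list alone. With 0 members past the threshold over all genes, vitellogenins (adjusted p = 0.00379; adjusted p = 0.423 with an estimated correlation), cuticle collagens (1.14e-12 and 0.170), muscle markers (0.00467 and 0.590), ribosomal proteins (0.0187 and 0.788) and pharynx gland and cuticle genes (0.0267 and 0.503) lay lower. Adjusted over the list alone 1 vitellogenin and 2 pharynx genes fell, and 0 genes passed in the other lists. Among the members that did not pass, col-10, col-65, col-113 and col-167 had log2 differences of −1.24, −1.77, −0.69 and −1.89 (adjusted p = 0.320 to 0.530), abu-14 −1.11 and vit-5 −0.18 (adjusted p = 0.818 and 0.0858). The ribosomal call was lost without control replicate 3 or GONH2 replicate 1, the muscle call without control replicate 1 or 2 or GONH2 replicate 3, and the pharynx call without control replicate 2 or GONH2 replicate 1 or 2 (adjusted p up to 0.965, 0.0667 and 0.168). With array weights the ribosomal, muscle, pharynx and vitellogenin calls were lost. The ribosomal call was also lost without the filter on low values. Requiring at least 5 FPKM, or using the replicate number as a block, lost the pharynx call. Of the 37 lists 10 were called, 0 with an estimated correlation and 4 by fry, namely lysozymes, proteases, C-type lectins and genes lowered by DAF-16; 12 had an unadjusted p under 0.05. In 5 of the 10 the library medians overlapped with control: vitellogenins, ribosomal proteins, muscle markers, and PMK-1-dependent and pharynx genes. The 27 lists not called had adjusted p values from 0.0600 to 0.851. Of the 25 calls of named genes, 9 stayed at adjusted p under 0.05 in each refit that kept the gene (20 for cel-mir-8199, 22 for asm-3, 23 for the others), those of clec-62, clec-85, clec-150, clec-50, lys-7, asp-1, asm-3, pcp-1 and cel-mir-8199, for the last of which no refit tested the listed zeros. All 9 had adjusted p under 0.01 with all libraries, and 2 changed at least 2-fold. Leaving out control replicate 1, 2 or 3 lost 13, 8 and 13 of the 25, GO replicate 1, 2 or 3 lost 6, 12 and 8, and GONH2 replicate 1, 2 or 3 lost 15, 16 and 13.

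The effects of both materials were set side by side to ask whether the same genes respond. Of the 56 genes called with GONH2, 52 were also called with GO, 43 higher with both and 9 lower with both, and 0 changed in opposite directions. The 52 became 24 without control replicate 1, 33 without GO replicate 2, and 23, 24 and 34 without GONH2 replicates 1, 2 and 3. If calls were independent, 0.498 higher and 0.0179 lower genes would be shared. That figure leaves the shared controls out of account. In 100 simulations of unchanged groups that share their controls, 0 genes were called in both. No effect was simulated there, so few calls could arise in either comparison. The simulations therefore cannot say how many shared calls common controls give beside real effects. Over all genes the effects correlated at r = 0.65 (Spearman's rho = 0.52), where the shared controls alone gave a mean r of 0.499 in the simulations; genes are not independent replicates. Among the shared genes were lys-7, lys-4, clec-62, clec-85, dod-19, srlf-3, spp-2, asp-1 and C17H12.8 (higher) and asm-3, clec-70, clec-218 and clec-5 (lower). Of the 139 genes higher with GO, 138 rose more with GO than with GONH2 (median change 0.63 and 0.36). Of the 46 genes higher with GONH2, 43 did (0.58 and 0.42). The change was larger with GO in 17 of the 23 genes lower with GO (median size 0.57 and 0.37) and in 5 of the 10 genes lower with GONH2 (0.90 and 0.74). By the F test 123 genes differed among the groups.

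**Figure D4:**
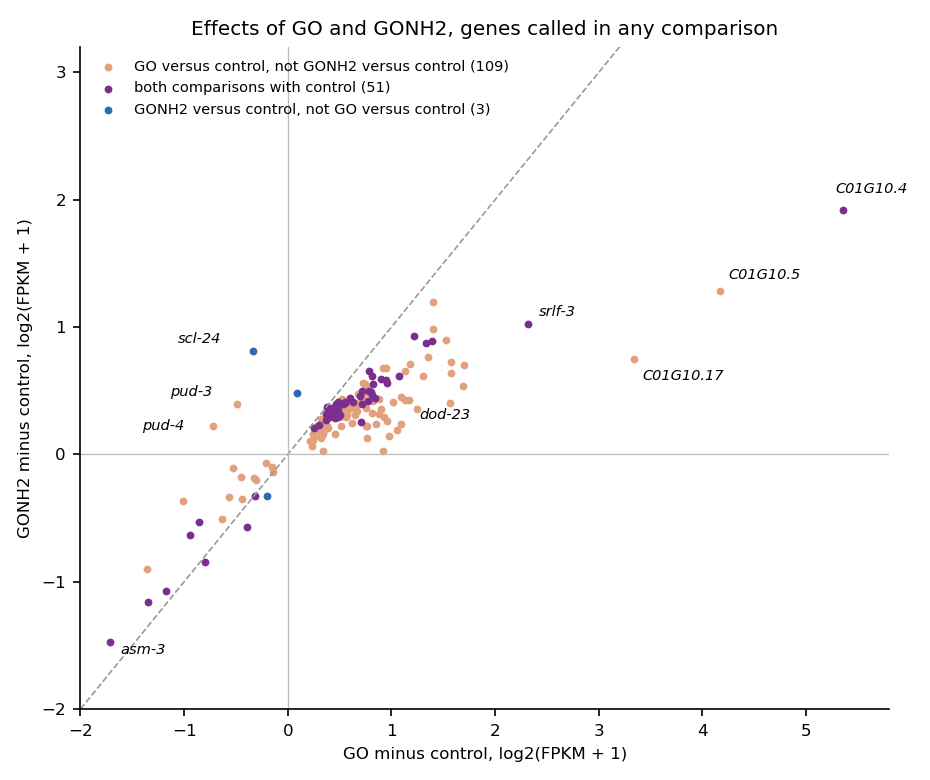
Change with GONH2 against change with GO, each minus control in log2(FPKM + 1), for genes called in either comparison; colours mark genes called with GO alone (109 shown), with both (51) or with GONH2 alone (3), and the dashed line marks equal change. The 3 called genes listed at 0 in 6 libraries are left out.

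The direct comparison of GONH2 with GO asks which genes differ between animals with either material. It called 5 genes higher and 12 lower in GONH2, of which 2 and 3 differed at least 2-fold, with 598 genes at an unadjusted p under 0.05 and groups that did not overlap in 1287 of 12849 genes, where chance gives 10%. Under median-of-ratios scaling the counts were 6 higher and 8 lower. srlf-3 had 12.0 ± 1.38 FPKM with GONH2 against 30.9 ± 3.15 with GO (−1.30 ± 0.13, adjusted p = 0.00852), and dod-23 had 206 ± 13.5 against 345 ± 26.1 (−0.74 ± 0.072, adjusted p = 0.00852). pqn-31, clec-85, clec-62, clec-65 and lys-7 were lower with GONH2 by log2 differences of −0.64, −0.46, −0.36, −0.32 and −0.28 (adjusted p = 0.0397, 0.0107, 0.0172, 0.0316 and 0.00725). pud-3 had 139 ± 15.5 FPKM in control, 98.5 ± 3.84 with GO and 183 ± 9.07 with GONH2 (0.88 ± 0.075, adjusted p = 0.00725). pud-4 had 73.1 ± 6.08, 43.9 ± 2.97 and 85.6 ± 8.67 (0.95 ± 0.088, adjusted p = 0.00798), and scl-24 had 0.618 ± 0.0711, 0.284 ± 0.136 and 1.84 ± 0.170 (1.15 ± 0.12, adjusted p = 0.0107). Without GONH2 replicate 3 all 10 named calls of this comparison were lost (adjusted p = 0.0543 for pud-3 and pud-4), and 0 genes were higher and 1 lower. Of the 10, leaving out GO replicate 1, 2 or 3 lost 5, 6 and 2, GONH2 replicate 1 or 2 lost 5 each, and control replicate 1 or 3 lost 1 each.

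Genes that depend on PMK-1 lay lower with GONH2 than with GO (camera adjusted p = 2.98e-05; adjusted p = 0.779 with an estimated correlation), with clec-85 passing over all genes and 4 falling when adjusted over the list alone; irg-4 and C17H12.8 did not pass (−0.42 and −0.45). C-type lectins lay lower too (camera adjusted p = 0.00678; adjusted p = 0.779 with an estimated correlation), with 0 higher and 3 lower over all genes and 1 and 10 adjusted over the list alone. Their call was lost without GO replicate 3 or GONH2 replicate 3 (adjusted p up to 0.133), without the filter on low values and with array weights. Sperm genes lay lower with 0 members past the threshold (adjusted p = 0.0299; adjusted p = 0.994 with an estimated correlation), but not when at least 5 FPKM were required, where they lay higher (adjusted p = 0.698). The sperm call was also lost with 0.1 added before the logarithm, with array weights and with the replicate number as a block. With 0 members past the threshold, oocyte and eggshell genes (adjusted p = 2.91e-04; adjusted p = 0.994 with an estimated correlation), vitellogenins (0.00216 and 0.779), germline genes (0.00216 and 0.994), ribosomal proteins (0.00216 and 0.994) and proteasome subunits (0.00458 and 0.994) lay higher. Adjusted over the list alone 2 vitellogenins were higher and 0 genes passed in the other 5 lists. The median was 0.022 for oocyte and eggshell genes, 0.11 for vitellogenins, 0.027 for germline genes and 0.011 for proteasome subunits. Over all genes it was −0.024. The ribosomal list had a median of 0.012 but a mean of −0.086, and lay lower without GO replicate 1 (adjusted p = 0.110). Each of these 6 calls was lost without at least 1 library: GO replicate 1 for vitellogenins, GONH2 replicate 1 for oocyte and germline genes, GO replicate 1 or GONH2 replicate 2 for proteasome subunits, these or GONH2 replicate 3 for ribosomal proteins, and GO replicate 1 or 3 or GONH2 replicate 1 or 3 for sperm genes. The adjusted p values then reached 0.0864, 0.0555, 0.638, 0.163, 0.224 and 0.760 for vitellogenins, oocyte, germline, proteasome, ribosomal and sperm genes. Lysozymes were not called (camera adjusted p = 0.410; lys-7 alone lower), nor proteases (0.0812; median −0.052, mean 0.091; 0 genes past the threshold and 2 lower when adjusted over the list alone), nor genes lowered by DAF-16 (0.0724; dod-23 lower, and 1 higher and 3 lower when adjusted over the list alone). Of the 37 lists 8 were called, 0 with an estimated correlation and 0 by fry; 11 had an unadjusted p under 0.05. The library medians of GONH2 and GO overlapped in 6 of the 8, all but C-type lectins and PMK-1-dependent genes.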

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

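The contrast of GONH2 with GO was planned. Of the tests of explanations in this part, those of the pud genes, of the size of the response and of the genes on chromosome V were chosen only after the results were seen.

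The effects of GO and GONH2 differed, by the direct test of GONH2 minus GO, in 17 genes. In 11 of them the estimate with GONH2 had the sign of that with GO and was smaller; dod-23 (0.43, adjusted p = 0.0555) and pqn-31 (0.45, 0.0909) did not pass in GONH2 versus control. For srlf-3 the log2 difference was −1.30 (adjusted p = 0.00852), for dod-23 −0.74, for pqn-31 −0.64, for lys-7 −0.28 and for the C-type lectin genes clec-85, clec-62 and clec-65 −0.46, −0.36 and −0.32. The genes without a symbol C01G10.4, F32A5.4, C14C6.5 and C14C6.2, named after their values were seen, differed by −3.44, −0.45, −0.40 and −0.35. In pud-3 (0.88), pud-4 (0.95) and scl-24 (1.15) the estimates against control had opposite signs, but only 1 of the pair passed in each gene: scl-24 did not pass with GO (−0.34, adjusted p = 0.474), and the pud genes are taken up below. The size for scl-24, a gene of low FPKM, depends on the value of 1 added to FPKM and ranged from 1.07 to 2.39 over the refits. Also chosen after their values were seen, Y69H2.3 differed by 0.39, and a pair of genes had groups listed at 0, so that their differences depend on the added value too. F55H12.9 (−1.97) was listed at 0 in all control and GONH2 libraries and at 5.32, 2.28 and 1.89 FPKM with GO. Y46E12A.5 (1.15) was listed at 0 in all control and GO libraries and at 1.43, 1.16 and 1.09 FPKM with GONH2.

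Of the 46 genes called higher in GONH2 than in control, 43 had a larger rise with GO. These genes were chosen by their GONH2 result, which favours GONH2, so the choice of genes by their GO result is argued against as the whole source. Over the same 46 genes the median ratio of the GONH2 to the GO effect was 0.709; it stayed at 0.746 or below under median-of-ratios scaling and quantile normalization, and at 0.756 or below with any 1 of the 9 libraries left out, so neither scaling nor 1 library accounts for it. Among falls the picture depends on the choice of genes: the change was larger with GO in 17 of 23 genes lower with GO (median ratio 0.663) but, leaving out cel-mir-8199 (at 0 in all libraries of both materials), in 5 of 9 genes lower with GONH2 (0.912). A smaller amount of GONH2 reaching the animals (the dose is not stated in the sources used here) or a weaker effect of the amino-functionalised sheets stays open for the genes that rose; neither was tested, and the genes are not independent of each other.

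The genes pud-3 and pud-4 fell with GO (−0.49 and −0.72, adjusted p = 0.0167 and 0.00454) and were not called with GONH2 (0.39 and 0.22, adjusted p = 0.0959 and 0.836). Reads moved between copies of the family would leave the family's sum level, but the length-weighted sum over 6 pud genes differed by 0.619 (log2, GONH2 minus GO). Genes named pudl, such as pudl-2, were not in the sum. The most abundant of the 6, pud-1.2, had 264, 284 and 258 FPKM with GO and 379, 348 and 351 with GONH2. In control it had 416, 395 and 353, and it was not called in GONH2 versus GO. For pud-3 and pud-4 at least 1.011 times the difference remained under median-of-ratios scaling and quantile normalization, which argues against scaling. A difference in how the animals respond to the materials stays open and was not tested further, and without GONH2 replicate 3 neither gene passed the threshold (adjusted p = 0.0543 for both, the highest over 23 refits, which began at 0.00158 and 0.00316).

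The adjacent genes C01G10.5, C01G10.4 and C01G10.17 were high in the GO libraries. Transcripts running on from the next abundant gene would pass through the genes in between, but the highest of these reached 7.11 FPKM in a GO library, below the lowest value of the 3 genes there, 11.9. A single transcript counted under C01G10.5 and C01G10.4 would keep their ratio, but it varied 2.451-fold over the GO libraries, and the genes lie on opposite strands. For C01G10.17 and C01G10.4, which share a strand, the ratio varied 1.246-fold, which cannot tell 1 transcript from 2. A response of the animals to GO may explain the rise, as may sequence shared with genes elsewhere, which was not tested.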

How the results depend on the processing

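Leaving out genes with an implausible zero, setting such zeros to missing, a robust prior variance and protein-coding genes only were chosen after the data were seen; the other settings were planned. Limits come from 3 libraries per group of unknown depth. The smallest simulated changes were called in 35.2% to 38.8% of genes, shares likely too high for the GONH2 comparisons. Genes that did not pass are therefore not shown to be unchanged. Named genes gave 2685 values on the same side of the threshold and in the same direction under planned settings, 264 that no longer passed, 24 that newly passed and 7 reversed; under added settings these were 610, 0, 12 and 1. The reversed values were in GONH2 minus GO and none was called: vit-6 (−0.0080) had 0.0207 with median-of-ratios scaling, 0.0578 with quantile normalization, 0.0082 with array weights, 0.0091 without GO replicate 3 and 0.0227 without GONH2 replicate 3 (from −0.0268 over libraries left out), vit-1 had −0.0326 without GO replicate 1 (up to 0.2819), and rps-12, listed at 0 in GONH2 replicate 3, had 0.0041 without that library (from −5.6549) and with zeros set to missing. No called gene turned its sign under any setting, the correlation of effects ranged from 0.526 to 0.733, and no added setting moved a count over 1.5 times. Sizes of genes with low FPKM depend on the value added before the logarithm. With GO, asm-3 reached −3.17, clec-70 −2.18, pudl-2 −2.07 and ifas-2 2.38 over the refits. The 2-fold counts and the order of the largest changes therefore hold for an added value of 1. Lists gave no value with zeros set to missing.

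With adjusted p under 0.01, GO versus control had 88 genes higher and 12 lower, GONH2 versus control 20 and 4, GONH2 versus GO 3 and 5, the F test 74, and 21 were called in both materials. Requiring 2-fold changes gave 28 and 6, 3 and 4, 2 and 3, and 6 in both; both settings only tighten the call. Array weights gave 71 genes higher in GONH2 than in control, 36 lower in GONH2 than in GO and 6 lists for GONH2. At least 5 FPKM gave 3 genes higher in GONH2 than in GO; no filter gave 27 higher and 5 lower for GONH2 versus control and 29 in both. A fit to the 6 libraries compared gave 27 and 6 for GONH2 versus control, with fewer degrees of freedom. Without a trend there were 22 and 5, 5 genes lower in GONH2 than in GO, and 24 in both. With the replicate number as a block, GONH2 versus control had 25 and 4, GONH2 versus GO 3 and 5, and 26 were called in both; the labels do not say that the numbers pair the samples. Apart from thresholds and fewer libraries, the cause was not tested. With an estimated correlation 0, 0 and 0 lists were called, and by fry 6, 4 and 0.

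Leaving out each library gave 92 to 144 higher and 15 to 26 lower for GO versus control, 20 to 47 and 4 to 11 for GONH2 versus control, 0 to 6 and 1 to 15 for GONH2 versus GO, at least 82 by the F test, 23 to 48 in both, and 12 to 15, 9 to 13 and 5 to 10 lists. GO versus control moved by over 1.5 times only without GO replicate 2 (92 and 15). For GONH2 versus control higher genes numbered 22 without control replicate 1, 30 without control replicate 3, 20 without GONH2 replicate 1 and 22 without GONH2 replicate 2; lower genes numbered 5 without control replicate 1 or GONH2 replicate 1 or 2, 6 without GO replicate 2 or 3 and 4 without GONH2 replicate 3. Genes called in both numbered 24 without control replicate 1, 33 without GO replicate 2, and 23, 24 and 34 without GONH2 replicates 1, 2 and 3. For GONH2 versus GO higher genes numbered 2 without GO replicate 1 or GONH2 replicate 2 and 0 without GONH2 replicate 3; lower genes numbered 7 and 3 without GO replicates 1 and 2, and 7, 6 and 1 without GONH2 replicates 1, 2 and 3. Lists for GONH2 versus GO numbered 5 without GO replicate 1.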

Other observations

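The tests of gene-name prefixes and of neighbouring genes in this part were chosen only after the results were seen, and the counts over other splits of the libraries were planned. Among 322 prefixes of gene symbols, the genes higher with GO than in control were enriched in 6 after adjustment, by Fisher's exact test. They were clec (13 of 77 tested genes, adjusted p = 5.24e-11), nspg (nematode-specific peptides of group G, 6 of 10, 1.83e-08), asp (5 of 11, 3.03e-06), ctsa (homologues of cathepsin A, 3 of 6, 0.00126), lys (3 of 7, 0.00175) and dod (3 of 8, 0.00232). The prefix spp did not pass (3 of 23, adjusted p = 0.0568). Among genes lower with GO, vit passed (2 of 5, 0.0198) and clec did not (3 of 77, 0.148). The test looked for over-representation only and treats genes as independent. It rests on the same calls as the lists above, so it adds no separate support. For C-type lectins, lysozymes and vitellogenins, camera with an estimated correlation gave adjusted p = 0.143.

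Outside the naming rule and chosen after their values were seen, gba-1 and gba-4 (glucosylceramidases) rose by 0.53 and 0.73 on the log2 scale with GO, and asah-2 (an acid ceramidase) by 0.37, while asm-3 (an acid sphingomyelinase) fell by 1.72. The cadmium-responsive gene cdr-4 rose by 0.76, and nuc-1 (a deoxyribonuclease II) fell by 0.21. Adjusted p was 0.00151, 0.00772, 0.00776, 0.00632 and 0.0168 for gba-1, gba-4, asah-2, cdr-4 and nuc-1. The metallothionein gene mtl-2 did not pass (log2 −0.33, adjusted p = 0.0693).

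Among the 139 genes higher with GO, 16 pairs were neighbours among the genes tested, against a mean of 1.48 and a highest of 8 in 10000 random draws (permutation p = 0.0001, one-sided, the smallest they can give). Leaving out pairs that share a symbol prefix left 10, against a mean of 1.42 and a highest of 8 (permutation p = 0.0001, the smallest they can give). Of these 10, 0 had a symbol prefix in both genes, so copies of 1 family side by side could not be told from unrelated neighbours. Shared regulation of neighbouring genes may contribute and was not tested. Neighbours such as clec-62, clec-63 and clec-65 on chromosome II, spp-3 and spp-2 on X, and asp-6 and asp-12 on V share a symbol prefix. They are not among the 10, and they cannot tell shared regulation from copies of 1 family side by side.

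Zeros of single libraries fell in abundant genes: rps-24 and rps-12 were listed at 0 in GONH2 replicate 3, where the other libraries had at least 3214.6 and 2466.9 FPKM, and him-3 was listed at 0 in GO replicate 2 against at least 80.2 elsewhere. The genes of the hypoxia list lay above their mean over the 9 libraries in replicate 1 of each group, by medians of 0.24, 0.31 and 0.24 (log2) in control, GO and GONH2. Replicate 1 of each group was also the highest for genes raised by DAF-16 (0.26, 0.35 and 0.098) and for metal and iron response genes (0.20, 0.33 and 0.011). These lists were picked out of the 37 for this pattern, so they do not show that the numbers mark a batch. Among libraries of the other groups, 3 of the 9 libraries correlated best with 1 of their own number, no more than unpaired numbers would give. Over the 12775 tested genes without an implausible zero, deviations from the group mean correlated by −0.11 to 0.25 between libraries of the same number. Between libraries of different numbers they correlated by −0.35 to 0.35. Genes are not independent replicates, and whether the numbers pair the samples stays open.

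With 10 splits of 6 libraries no share under 0.05 can be reached. The real split gave 162 genes for GO versus control against 11 in the highest other, 56 against 3 for GONH2 versus control, and 17 against 4 for GONH2 versus GO. For the 37 lists the real splits gave 13, 10 and 8 calls, and the others 6 to 12, 6 to 14 and 1 to 9. As many lists as in the real split came from 1, 4 and 4 of the 10 splits. The number of lists called at the preset correlation therefore hardly tells the real groups from other splits. Over 100 splits of the 9 libraries, the F test gave 123 genes against 50 at most in another split, and genes called in both materials numbered 52 against 5. In each case 1 of the 100, the real one, gave a result as large, the smallest share they can give. This argues against a random grouping of independent libraries. It cannot speak to chance differences between cultures, since separate growth of the replicates is not stated. Splits that only rename the real groups were not drawn, although the count called in both depends on which group is the control.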
